A study of Mus musculus with 22 samples.

How the data were processed

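The study profiled endothelial cells sorted from the retinas of mouse pups at postnatal day 6. The labels give that age, and their cell type entry also calls the cells adult, a conflict that was left as it stands. Per the labels, pups carried floxed S1pr1 and S1pr2 alleles on an S1pr3-null background, with the Rosa26-CreERT2 recombinase (gTKO) or without it (control), and both genotypes received 100 µg tamoxifen by injection. S1pr1, S1pr2 and S1pr3 encode G protein-coupled receptors for sphingosine 1-phosphate, a circulating lipid mediator. Each replicate pooled the retinas of several pups, per the series description. ATAC-seq, in which the Tn5 transposase cuts and tags accessible DNA, was carried out on 3 control and 3 gTKO libraries. The series also lists 16 RNA-seq libraries, from these genotypes and from mice with or without endothelial Junb, which are not analysed here.

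The values analysed are the positions of ATAC-seq peaks in 2 lists deposited by the authors, 1 per genotype. The labels of all 3 libraries of a genotype name the same list. Whether its peaks were called on pooled reads is not given in the sources used here. Each list has 3 columns, sequence name, start and end, and holds no score, fold enrichment, p or q value or summit. Per the submitters' processing notes, the tools named across the series include Bowtie2, Picard, MACS2, bedtools, edgeR and HOMER, and the build is mm9. The calling threshold and any filter on duplicate or blacklisted reads are not given in the sources used here. In both lists no peak was under 150 bp wide, 1454 control and 1324 gTKO peaks were exactly that wide, and no gap between neighbouring peaks was under 11 bp. The read depth of the libraries is not known from these lists, and a list made from fewer reads or with lower signal over background would hold fewer and narrower peaks. On 10 of 21 chromosomes the last peak of each list lay beyond the last gene annotated in GRCm38. On chromosome 7 the last control peak ended at 152488919 and the last gene at 145324059. Chromosome lengths were not compared, and a peak can lie past the last gene, so the build rests on the processing notes. An mm9 sequence or annotation was not used here. Regions are therefore named by position only, and the planned comparisons of promoters, gene lists and sequence motifs, AP-1 included, were not run.

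Peaks that overlapped or touched within a list were to be merged with bedtools 2.31.1, which changed no peak. Comparisons used regions on chromosomes 1 to 19, X and Y. This left out 1044 control and 620 gTKO peaks on unplaced sequences, which are described at the end. A region was shared if it overlapped a region of the other list by at least 1 bp, and otherwise belonged to the control-only or gTKO-only class. The plan ranked regions by fold enrichment. Since the lists hold none, width took its place, a choice made after seeing the data. Width depends on threshold and depth, so it is a poor stand-in for signal. Shares have exact 95% Clopper-Pearson intervals, which cover counting error only, treat regions as independent, and do not cover variation between animals.

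With 1 list per genotype there is no replicate error, and no p-value between genotypes is given. To describe position, the observed class labels were dealt at random 10000 times over the regions of a list within 10 groups of equal size by width, and the number of one-list regions per chromosome or 1 Mb window was set beside these draws. The draws show what an even loss along the genome would give. They do not measure the difference between genotypes. Overlap by position alone was estimated by rotating the gTKO list along each chromosome 100 times. The procedure was tested on simulated data made from the 57267 placed control regions. All 20429 regions dropped evenly were recovered as one-list regions, with 1 of 2336 windows above all 1000 draws. Kept regions were trimmed at their start by less than the smallest width, so this recovery was fixed in advance. The simulated lists held no split regions and none particular to the second list, unlike the real ones. With 5 planted windows of extra loss, all 5 lay above all 1000 draws, as did no other window. The planted loss was large and was set only in windows with many regions. Some windows reported below held few regions, as few as 12 in the gTKO list, and detection in such windows was not tested. By a rule fixed before the data were examined, the 10 leading regions of each class are named, here by width. Shared regions were ranked by their width in the control list. Alternatives for the overlap rule, the set of sequences, the size of windows and the group of leading regions were listed before the data were examined. Alternatives that need a summit or a q value were not run. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.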

Results

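ATAC-seq peaks of retinal endothelial cells were compared between pups that kept S1pr1 and S1pr2 (control, 3 libraries) and pups in which the tamoxifen-dependent recombinase targeted both (gTKO, 3 libraries). S1pr3 was absent in both genotypes. Each genotype is represented by a single peak list, so the values below describe these lists and have no replicate error. The read depth behind each list is unknown. The control list held 58311 peaks and the gTKO list 50178 peaks. On the placed chromosomes, 57267 control regions covered 31.4 Mb and 49558 gTKO regions covered 24.2 Mb. The median width was 359 bp (quartiles 212 and 735 bp) in the control list and 337 bp (quartiles 209 and 645 bp) in the gTKO list.

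The first comparison asked which accessible regions were called in both genotypes and which in one. Most regions were shared, and the regions called in one genotype lay mainly in the control list. Of the control regions, 41796 (73.0%) overlapped a gTKO region, and of the gTKO regions, 44728 (90.3%) overlapped a control region. The control-only class held 15471 regions, 27.0% of the control list (95% interval 26.7 to 27.4%). The gTKO-only class held 4830 regions, 9.75% of the gTKO list (95% interval 9.49 to 10.0%), so control-only regions were 3.20 times as numerous. The shared sequence amounted to 22.5 Mb, which was 71.5% of the control coverage and 92.8% of the gTKO coverage. After rotation of the gTKO list along the chromosomes, 1.86% of control regions overlapped it on average (range 1.65 to 2.11%). When the control list was reduced to its widest regions, as many as in the gTKO list, 9993 regions were control-only and 6912 gTKO-only, a ratio of 1.45. That setting also raises the smallest width kept in the control list alone. With equally many regions per list, the 2 counts can differ only through overlaps that were not 1 to 1. The ratio of 1.45 therefore does not count additional control loci. With regions of at least 300 bp in both lists, the numbers were 8158 and 1863, a ratio of 4.38. That cut also removes partners under 300 bp, so these counts include regions that overlapped a narrower region of the other list. In the full lists, 2119 control regions of 300 to 499 bp, 474 of 500 to 999 bp and 41 wider ones had no partner. The gTKO numbers were 444, 16 and 0.

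Regions called in one genotype were narrow. Control-only regions had a median width of 194 bp (quartiles 163 and 257 bp) against 508 bp for control regions with a partner. gTKO-only regions had a median width of 185 bp (quartiles 160 and 228 bp) against 376 bp for gTKO regions with a partner. Control-only regions made up 11.5% of the sequence covered in the control list, and gTKO-only regions 4.12% of that in the gTKO list. Within the width class of 150 to 199 bp, 33.6% of control regions (95% interval 32.8 to 34.5%, of 12300) and 73.8% of gTKO regions (95% interval 73.0 to 74.6%, of 10997) had a partner. Between 300 and 499 bp these shares were 80.9% (80.2 to 81.7%) and 95.7% (95.3 to 96.1%). From 1000 bp upwards, 8697 of 8738 control regions and all 5348 gTKO regions had a partner. At each of the 5 width classes the control list had the lower share, with intervals that did not overlap. Equal width does not match loci between the lists. As described below, control regions were mostly wider within pairs and some spanned several gTKO regions. A narrow gTKO region can thus be part of a wide control region. The control list also covered more sequence, which makes a partner more likely for gTKO regions.

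**Figure D1:**
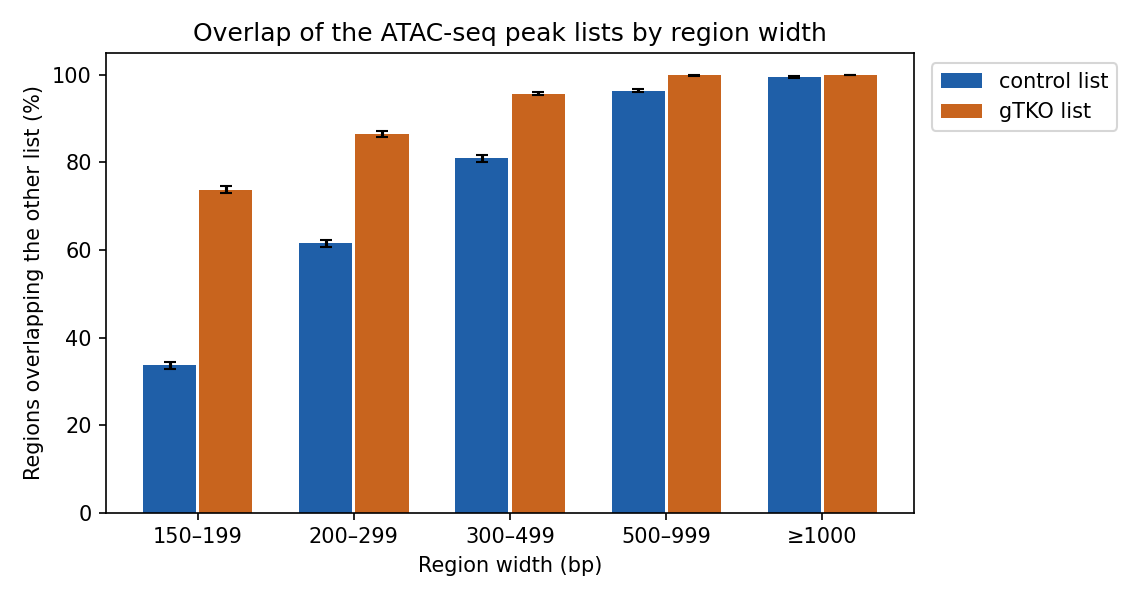
Share of regions that overlapped a region of the other list (y axis, percent) by region width (x axis, bp), for the control list (blue) and the gTKO list (orange). Bars show the share and error bars the exact 95% interval, which covers counting error only. The share rose from 33.6% to 99.5% in the control list and from 73.8% to 100% in the gTKO list.

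Shared regions were mostly wider in the control list. Among 37878 regions that matched a single region of the other list, the control region was wider in 30110 pairs (79.5%, 95% interval 79.1 to 79.9%), the gTKO region in 7548, and the widths were equal in 220. The median width was 476 bp in the control list and 378 bp in the gTKO list, and the median ratio within pairs was 1.15. A control region spanned 2 or more gTKO regions in 3021 cases, and a gTKO region spanned 2 or more control regions in 529 cases. The shared regions named next were ranked by control width alone, which favours examples that were wider in that list. They illustrate the counts above and do not add to them. The widest shared region, on chromosome 2 from 26448600 to 26461312 (12713 bp, mm9), was a single control region that held 10 gTKO regions covering 9141 bp. On chromosome 8, the control region from 87496961 to 87504520 (7560 bp) held 6 gTKO regions covering 5950 bp. The next widest control region, on chromosome 8 from 73236164 to 73242758 (6595 bp), held 8 gTKO regions covering 2498 bp. On chromosome 5, the control region from 143646795 to 143652146 (5352 bp) overlapped 3 gTKO regions covering 493 bp. By contrast, the control region on chromosome 17 from 34254687 to 34260137 (5451 bp) held 1 gTKO region covering 5090 bp. On chromosome 10, the control region from 79610307 to 79616115 held 4 gTKO regions covering 5350 bp of its 5809 bp. The others were on chromosome 3 from 95475978 to 95482205 (3115 of 6228 bp covered by gTKO regions), chromosome 15 from 101105347 to 101110869 (1360 of 5523 bp), chromosome 1 from 135966203 to 135971533 (941 of 5331 bp) and chromosome 17 from 71197964 to 71203244 (4775 of 5281 bp). The widest 10 shared regions ranged from 5281 to 12713 bp in the control list, and no placed gTKO region was wider than 5090 bp.

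The next comparison took the wide regions, which were the least often missed. Of the widest 10% of the control list (5726 regions of at least 1195 bp), 26 had no partner in the gTKO list, which is 0.454% (95% interval 0.297 to 0.665%). Of the widest 10% of the gTKO list (4955 regions of at least 1029 bp), 0 lacked a partner, which allows a share of up to 0.0605% by 3 counts of the total (exact upper limit 0.0744%). The 10 widest control-only regions measured 1776 to 3231 bp and lay on 5 chromosomes. The widest, on chromosome 8 from 74852875 to 74856105, was 2969 bp away from the nearest gTKO region, and a further control-only region followed from 74856215 to 74858069 (1855 bp). The others that exceeded 2 kb were on chromosome 8 from 124347810 to 124350718 (2909 bp), chromosome 7 from 135151963 to 135154345 (2383 bp), chromosome 8 from 73230785 to 73233065 (2281 bp) and chromosome 5 from 143652315 to 143654462 (2148 bp). The remaining regions were on chromosome 2 from 26464112 to 26466107 (1996 bp), chromosome 7 from 19871276 to 19873132 (1857 bp), chromosome 3 from 95487227 to 95489051 (1825 bp) and chromosome 8 from 11819092 to 11820867 (1776 bp). Of these 10 regions, 4 lay within 10 kb of one of the 10 widest shared regions, at gaps of 168 to 5021 bp. The 10 widest gTKO-only regions were narrower, at 539 to 672 bp, and lay on 9 chromosomes. The widest were on chromosome 18 from 39400865 to 39401536 (672 bp), chromosome 7 from 46552234 to 46552871 (638 bp) and chromosome 8 from 120946409 to 120947005 (597 bp). The remaining regions were on chromosome 14 from 41808481 to 41809067 (587 bp), chromosome 3 from 131354244 to 131354824 (581 bp), chromosome 11 from 46749663 to 46750220 (558 bp) and from 71575238 to 71575789 (552 bp), chromosome 10 from 107975432 to 107975975 (544 bp), chromosome 13 from 79137832 to 79138371 (540 bp) and chromosome 15 from 91305106 to 91305644 (539 bp). The median distance to the nearest region of the other list was 3.76 kb for all control-only regions and 5.99 kb for all gTKO-only regions.

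The share of one-list regions differed between chromosomes by a few percentage points, more often than the width-matched draws gave. On the 20 chromosomes other than Y, the control-only share ranged from 23.9% on chromosome 19 (95% interval 21.9 to 26.1%) to 31.3% on chromosome 15 (29.5 to 33.2%), and it was 30.9% on chromosome X (28.4 to 33.4%). The width-matched draws gave a mean of 28.8% on chromosome 15 and 28.0% on chromosome X. Chromosome 1, at 25.1% (23.7 to 26.6%) against a mean of 27.7%, had fewer control-only regions than any draw, and no chromosome had more than every draw. With both lists cut to regions of at least 300 bp, chromosome 1 no longer lay below every draw (459 control-only regions, lowest draw 442) and chromosome 13 did (290, lowest draw 291). This cut, also used for the chromosome counts below, labels regions as one-list if their only partner was under 300 bp. It therefore describes a different class and does not check the one defined above. Of the 20 chromosomes, 6 lay in the upper 2.5% of their draws and 5 in the lower 2.5%. With regions of at least 300 bp, 3 of the former (2, 9 and 15, but not X) and 3 of the latter (1, 13 and 18) still did. Chromosome counts include the 1 Mb windows described below. Windows with more control-only regions than every draw lay on chromosomes 2, 9 and 15, and also on other chromosomes. The higher shares on these 3 chromosomes are therefore not separate from such local windows. The gTKO-only share ranged from 7.69% on chromosome 11 (6.84 to 8.61%) to 12.7% on chromosome 14 (11.3 to 14.3%), against draw means of 9.20% and 10.2%. Here 3 chromosomes (1, 13 and 14) lay in the upper 2.5% of their draws and 3 (2, 11 and X) in the lower 2.5%. With regions of at least 300 bp these were 1 and 8 in the upper and 11, 17 and X in the lower 2.5%. Chromosome Y held 6 control and 8 gTKO regions, too few to compare.

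Within chromosomes, a small number of windows held more control-only regions than their widths would give, although most of the class lay elsewhere. In 25 of 2336 windows of 1 Mb, control-only regions were more numerous than in every one of the 10000 width-matched draws. A set of 1000 further draws gave 0.078 such windows on average and at most 2. The 25 windows held 1163 control-only regions, 7.52% of the class. With the wider 50% of the list alone, 9 windows exceeded every draw. In 4 windows control-only regions were fewer than in every draw, and gTKO-only regions were so in 0. The highest number, 85 of 159 control regions, was found on chromosome 8 between 11 and 12 Mb, against a draw mean of 51.6 and a highest draw of 70 for that window. The window on chromosome 4 between 118 and 119 Mb held 74 control-only regions of 122, against a draw mean of 36.7. On chromosome 5 between 32 and 33 Mb, 45 of 70 control regions were control-only (draw mean 21.3), and on chromosome 2 between 119 and 120 Mb, 48 of 102 (draw mean 25.2). In the chromosome 4 window, the stretch from 118778204 to 118834794 held 63 control regions, of which 53 were control-only, and 14 gTKO regions. The control list covered 26725 bp of this stretch and the gTKO list 6343 bp. This stretch was chosen for display after its values were seen.

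**Figure D2:**
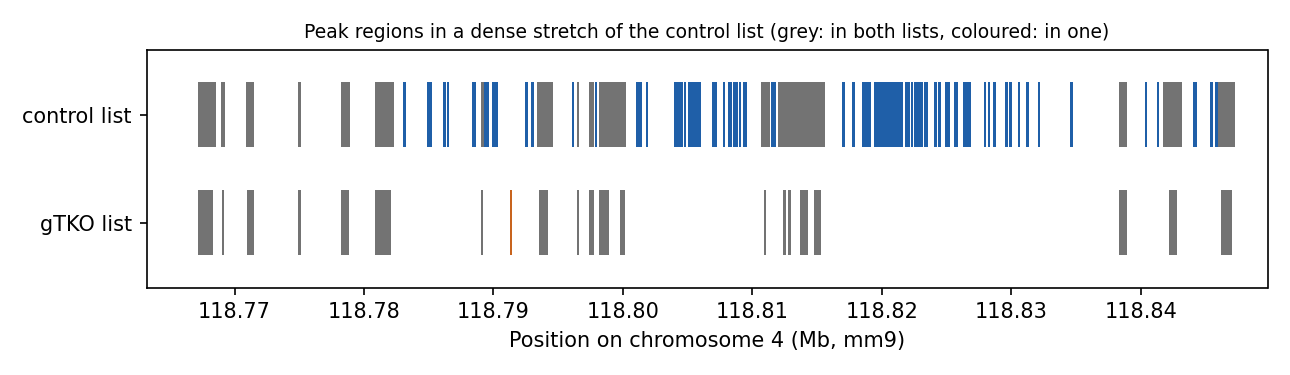
Map of the stretch on chromosome 4 (x axis, position in Mb, mm9), with the regions of the control list above and of the gTKO list below, drawn to scale. Grey regions overlapped the other list, blue regions were control-only and orange regions gTKO-only. Of the 63 control regions between 118778204 and 118834794, 53 were control-only.

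gTKO-only regions also exceeded the draws in a few windows. In 10 of 2302 windows they were more numerous than in every draw, and with the wider 50% of the list alone in 2 windows. Further draws gave 0.071 such windows on average and at most 2. A pair of adjacent windows on chromosome 4, between 145 and 147 Mb, held the most, with 49 of 159 and 51 of 191 gTKO regions against draw means of 24.5 and 29.1. On chromosome 7 between 46 and 47 Mb, 33 of 59 gTKO regions were gTKO-only (draw mean 7.86). On chromosome 14 between 44 and 45 Mb, 23 of 36 were gTKO-only (draw mean 5.95), and on chromosome 13 between 12 and 13 Mb, 22 of 45 (draw mean 7.38). The 10 windows held 226 gTKO-only regions, 4.68% of the class, and the rest lay elsewhere. Neighbouring regions are not independent, so a window beyond all draws is a description of these lists and not a test of genotype.

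**Figure D3:**
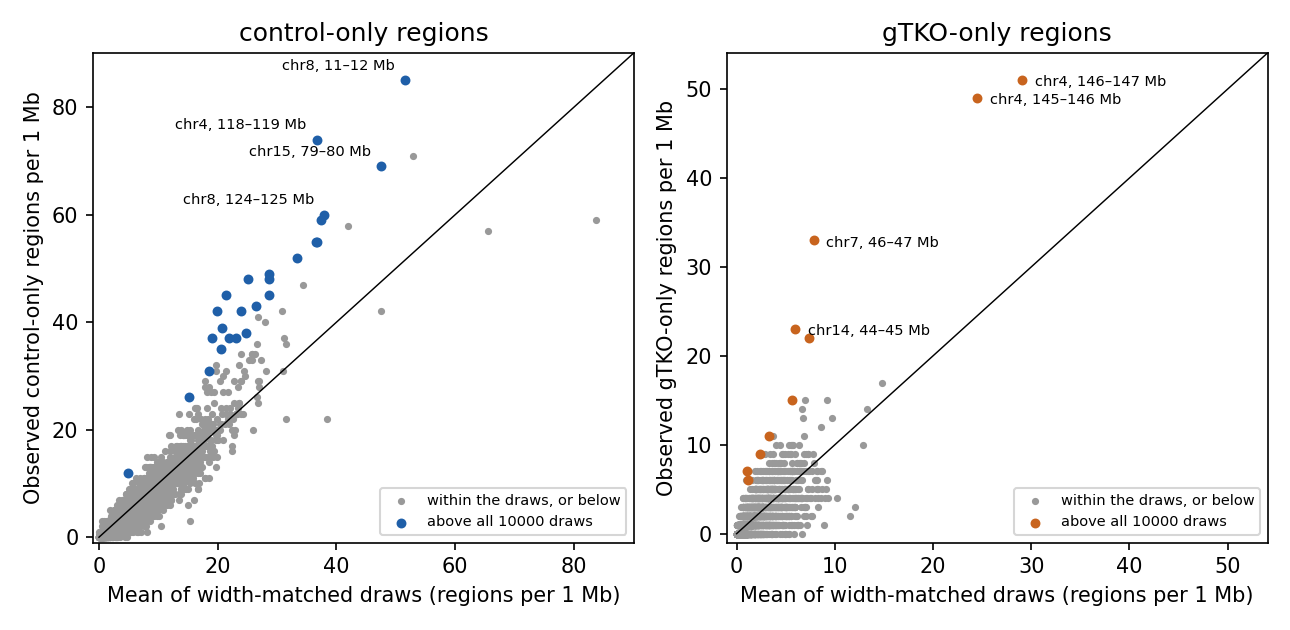
Control-only (left) and gTKO-only (right) regions per 1 Mb window (y axis, observed number) against the mean of 10000 width-matched draws (x axis, regions per window). Each point is a window, coloured points lie above all draws, and the line marks equal values. The chromosome 8 window from 11 to 12 Mb reached 85 control-only regions, and the chromosome 4 window from 146 to 147 Mb reached 51 gTKO-only regions.

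On unplaced sequences, which were left out above, the lists differed most on the sequence that gathers contigs with no chromosome (chrUn_random). It held 490 control regions covering 147 kb and 104 gTKO regions covering 23.1 kb. All 104 gTKO regions overlapped a control region, while 398 control regions had no partner. On contigs assigned to chromosome 8 without a position, 208 control regions covered 147.0 kb and 201 gTKO regions covered 149 kb. On those assigned to chromosome 1, 264 control regions covered 83.1 kb and 252 gTKO regions 78.0 kb.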

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

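Control-only regions outnumbered gTKO-only regions under all 7 alternatives, with ratios from 1.45 to 4.38 against 3.20. The control list is the larger one, which favours this direction, so agreement between the settings is weak support. Unmerged peaks repeat the main counts, since merging changed no peak, and so are no separate check. Requiring 50% of both regions to be covered gave 19916 control-only and 12207 gTKO-only regions. Keeping regions of at least 300 bp in both lists gave 8158 and 1863, which include regions whose only partner was under 300 bp. Keeping the widest regions, equally many per list, gave 9993 control-only and 6912 gTKO-only regions, which can differ only through overlaps that were not 1 to 1. The last 2 settings were chosen after seeing the data. The other overlap rules, all sequences and unmerged peaks stayed within 1.5 times of the reported counts. Control regions without a partner numbered 116 in the widest 25% (gTKO: 1) and 6 in the widest 1000 (gTKO: 0), against 26 and 0 in the widest 10%. In the control list the share rose from 0.454% in the widest 10% to 0.810% in the widest 25%, which adds narrower regions, and narrower regions had a partner less often. Restricting windows to the wider 50% of each list, also chosen after seeing the data, left 9 windows with more control-only regions than every draw and 2 with more gTKO-only regions, with fewer regions tested. Windows of 500 kb gave 30 and 9. For the share of control-only regions in dense stretches, described under other observations, the difference from single regions was 28.6 points. It was 14.5 points with neighbours within 10 kb, 6.71 points within 20 kb and 31.9 points with stretches of 20 or more. With stretches chained in the gTKO list and set against all other control regions rather than single ones, the difference was reversed, at -7.15 points. That choice favours regions with a partner. No paired analysis was possible because each genotype has 1 peak list for its 3 libraries, and for the same reason no replicate could be left out. Settings that need a q value, a summit, an annotation or a sequence were not run. Depth is unknown and limits the narrow classes most, since regions near the calling limit in one list can fall short of it in the other.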

Other observations

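The control-only regions in dense stretches and the unplaced sequences were examined only after the lists had been seen, and the tests of even loss, wider regions, other contigs and chance placement of gTKO-only regions were chosen after their results. Those of list selection, of regions of at least 500 bp and of repeated sequence were set before their values were computed.

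Control-only regions were most frequent where the control list was densest. Regions no more than 3 kb apart were chained into stretches. Among 28344 control regions with no such neighbour, 23.0% were control-only (95% interval 22.6 to 23.5%). The share was 32.9% in stretches of 5 to 9 regions (31.5 to 34.3%), 48.1% in stretches of 10 to 19 (45.3 to 50.9%) and 54.9% in stretches of 20 or more (52.2 to 57.6%). With neighbours chained at up to 20 kb, the difference between stretches of 10 or more and single regions shrank from 28.6 to 6.71 points. Median widths were 372 bp for single regions and 306 bp in the longest stretches. There were 143 stretches of 10 or more control regions. On chromosome 8 from 11825195 to 11846304, all 28 control regions were control-only and the gTKO list held 0 regions. On chromosome 11 from 106614094 to 106634681, 26 of 27 control regions were control-only, and on chromosome 2 from 119136492 to 119182714, 32 of 42. On chromosome X from 92123143 to 92171902, 27 of 59 were control-only. The stretches named here on chromosomes 8, 11 and 2 lay in 1 Mb windows already reported as above every draw, and the one on chromosome X did not. Dense stretches thus in part repeat the window result and are no separate evidence against an even loss.

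An even loss of regions along the genome is argued against, since stretches of 10 or more held 1345 control-only regions and the highest of 10000 width-matched draws held 859. Narrow width does not account for it alone. The lists hold no score, so whether regions lay near the calling limit could not be tested. Among regions of at least 500 bp, 19.6% in such stretches were control-only (16.9 to 22.5%), against 1.31% of single ones (1.11 to 1.54%). Choosing stretches by the control list may contribute: in stretches chained in the gTKO list, 19.98% of control regions were control-only against 27.1% elsewhere, though that choice favours regions with a partner. With stretches chained from both lists together, control-only regions made up 89.7% of one-list regions in stretches of 10 or more (88.1 to 91.2%) and 70.2% of single ones (69.3 to 71.2%). Such stretches held 1370 control-only and 157 gTKO-only regions of 2754. The more numerous class thus helped to form them, so this chaining is not free of selection either. Loss of accessibility at these loci in gTKO cells stays open as a hypothesis, as do differences in depth, signal over background or sorted cells between the libraries, which 1 list per genotype cannot separate.

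The shortfall of gTKO regions on chrUn_random was larger than an even loss would give, with 398 control-only regions against a highest draw of 253. Wider gTKO regions do not account for it, as the gTKO list covered 15.7% of the control length there. Nor was signal lost on every unplaced contig, since the gTKO list covered 93.8% of the control length on the contigs of chromosome 1 and 101% on those of chromosome 8. The control regions were spread over 36 bins of 100 kb, with at most 50 in a bin. Different filtering of this sequence or different content of repeated DNA in the libraries were not tested, and no biological explanation was tested.

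The windows with many gTKO-only regions exceeded chance placement given width, since 10 windows lay above all 10000 draws of the same window and 1000 further draws gave at most 2 such windows. Repeated sequence with reads placed at random between copies was predicted to raise control-only regions in the same windows. In 0 of the 5 leading windows did the control-only count lie in the upper 2.5% of its draws. On chromosome 4 between 146 and 147 Mb it was 59, below every draw (lowest 61). Yet this count, and the 57 between 145 and 146 Mb, were among the 10 highest of all windows. On chromosome 13 between 12 and 13 Mb, 20 of 41 control regions were control-only (draw mean 18.5). The windows were chosen by their gTKO-only counts, and whether repeats raise both classes beyond the draws was not checked. The test therefore cannot exclude repeated sequence. Copy number or background strain differences between the animals, and an effect of genotype, were not tested and stay open.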
